A study of Homo sapiens with 39 samples.

How the data were processed

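The study measured RNA in sigmoid colon tissue, the last part of the large bowel before the rectum. It set people with metabolic dysfunction-associated steatotic liver disease (MASLD), a disease in which fat accumulates in the liver, against controls free of it. Per the labels, 39 libraries fall into 3 groups of 13 called Healthy, Steatosis and Fibrosis. Per the labels' protocols, RNA was taken from colonic tissue with TRIzol, ribosomal RNA was depleted, and stranded libraries were made with the Collibri kit from 500 ng of RNA and sequenced as read pairs on a NextSeq instrument. Depletion of ribosomal RNA keeps unspliced transcripts and histone mRNAs, which lack a poly(A) tail, so a gene's value can include intronic reads. The genome build was hg38, per the submitters' processing notes. The aligner, the counting method and the gene annotation were not given in the sources used here, so how reads shared by near-identical genes were divided is not known. Alpha globin, histone, ribosomal protein, immunoglobulin constant and small nuclear ribonucleoprotein genes have near-identical copies or pseudogenes, and their values are uncertain for that reason.

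The deposited table held 34583 genes with Ensembl identifiers, of which 34504 (99.8%) matched the symbol table. Its title calls the values raw counts, but the values were on a log2 scale: the deposited values were not whole numbers, and 8287 genes sat at the same floor of 5.20924 in all libraries. Steps above the floor followed the variance-stabilising transformation that is fitted with a dispersion trend of the form constant plus a term over the mean. That transformation was inverted from the floor alone, which gave normalised read counts. Within each library the deposited log2 values carried a scaling between libraries: median-of-ratios factors recomputed on the normalised counts were 1.00718 in every library. The most shared value above the floor in each library was taken as 1 read. Of 104 values shared by several genes, 100% were whole multiples of it within 0.01. These include the 1-read value itself wherever several genes shared it, so part of that share is fixed by definition. Only 8.02% of 204284 low values were whole multiples, as happens where each gene has its own scaling in each library. Whole reads could therefore not be recovered. The quasi-likelihood and Wald tests for counts, and the voom weights and surrogate variables, that had been planned for raw counts were not run, and limma on the deposited log2 values took their place.

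The library depth estimated from the 1-read steps ran from 4.53 to 7.31 M (mega) reads (median 6.17 M), and from 18253 to 19698 genes had a value above the floor. A log2 difference on the deposited scale is close to the log2 ratio of normalised counts for well expressed genes and is smaller than it for low ones, so changes of low genes are understated.

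Genes with a normalised count of at least 10 in at least 13 libraries were tested, which left 15958 genes. Linear models were fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3, with group as the only term, all 39 libraries in 1 fit, and empirical Bayes moderation with a mean trend and robust estimation. The 4 contrasts were all two-sided: MASLD against Healthy (the mean of the Steatosis and Fibrosis groups minus Healthy), Steatosis against Healthy, Fibrosis against Healthy, and Fibrosis against Steatosis. P values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Groups, contrasts, gene lists and the first set of alternatives were fixed before the data were examined; the switch from count models to limma was not. The labels give no batch and no pairing. In the order of the labels, the libraries from Fibrosis 4 to Fibrosis 13 all come after the last Healthy and Steatosis library. Any drift along that order is therefore largely mixed with the Fibrosis label. The order was tried as a covariate among the alternatives.

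Gene lists for mucus and barrier, defence, immune and stromal cells, epithelial cell types, metabolism and RNA quality numbered 41, and 40 had at least 5 tested genes. The list left untested held structural noncoding RNAs, which were not analysed here. Lists were tested with limma's camera, which asks whether a list's genes moved more than the other genes, at a preset correlation between genes of 0.01. Each call was repeated with the correlation estimated from the data, with fry, which asks whether a list's genes moved on balance in 1 direction or in either direction, and with 100000 permutations of the libraries on each list's mean score. A score is the mean of the list's log2 values after centring each gene. P values were adjusted over the 40 lists. Members that passed when adjusted over the list alone were counted too.

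The rule for named genes gave, in each contrast, the 5 genes with the smallest p in each direction where none passed the threshold. It further gave up to 4 members with the smallest p in each list described, and a fixed set of genes for mucus, junctions, bacterial sensing and defence, of which 1 was not analysed here. Genes on the Y chromosome, XIST and TSIX, and the variable, diversity and joining segments of antigen receptors were never named (106 of the genes tested). Members that passed over their list alone are named as well, which was chosen after their values were seen. Coordinates came from GENCODE release 29 on GRCh38, matched on the identifier without its version, for 15925 of the tested genes, and are 1-based.

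The limma and camera steps were first tested on simulated data made from the real residuals with libraries shuffled. For limma, 200 genes were changed at once by known folds, 50 at each fold. Fry, the permutation tests, and the contrasts of Steatosis with Healthy and Fibrosis with Steatosis were not simulated. Over 20 simulations of MASLD against Healthy on the 15958 genes, limma recovered 32.9% of genes changed 1.25-fold, 70.0% at 1.5-fold, 89.5% at 2-fold and 95.8% at 3-fold, and 3.87% of its calls were false. For Fibrosis against Healthy the shares were 21.0%, 60.9%, 84.6% and 94.6%, with 3.94% false. With 1 list lowered 1.25-fold at a time, camera at the preset correlation recovered it in 94.2% of runs but called on average 11.2 other lists that had not been changed. With an estimated correlation it recovered 56.7% and called 0.0583 others. Library measures were compared with permutation tests (100000 resamples, two-sided), adjusted over 30 comparisons. Figures were drawn with matplotlib 3.10.9. Alternatives covered the gene filter, scaling, transformation, covariates, the replicate number as a block, array weights, sets of libraries and leaving out each library in turn.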

Results

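Sigmoid colon RNA was profiled in 13 Healthy, 13 Steatosis and 13 Fibrosis libraries, and 15958 genes were expressed highly enough to test. Values are normalised read counts given as mean ± SD over 13 libraries, and differences are on the deposited log2 scale with their standard error (SE). The labels number the libraries within a group and do not say that each came from a different person, so p values measure the spread between these samples. Estimated depth ran from 4.53 to 7.31 M (mega) reads per library, and 18253 to 19698 genes were detected. Pairs of libraries correlated across genes with Pearson r between 0.876 and 0.975, and no library repeated another. The first principal component held 14.3% of the variance and the second 6.43%, and neither differed between groups in permutation tests. Along the first, Fibrosis 6 lay at 73.2 while the other libraries ranged from -14.3 to 16.1. That library had 0.0709% of its reads in immunoglobulin constant genes, the product of plasma cells, against 0.708% to 3.44% in the others. Its ribosomal protein mRNAs took 0.50% of reads (others 1.28% to 2.04%), its mitochondrial mRNAs 9.08% (others up to 7.32%), and its estimated depth was 6.13 M reads.

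**Figure D1:**
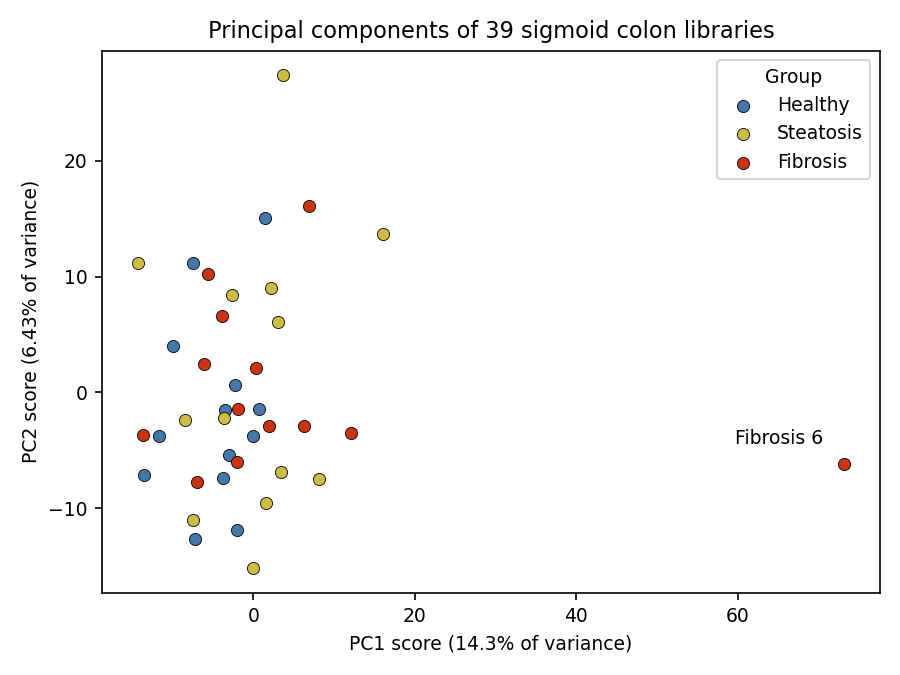
Scores of the 39 libraries on the first (14.3% of variance) and second (6.43%) principal components of the tested genes, 1 point per library, coloured by group. Fibrosis 6 lies at 73.2 on the first component, and the other libraries between -14.3 and 16.1 with the 3 groups intermixed.

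The first comparison asked how colon of people with MASLD differed from that of disease-free controls. The bile salt export pump gene ABCB11 had 67.2 ± 29.6 normalised reads in Healthy, 100.4 ± 24.7 in Steatosis and 113 ± 24.7 in Fibrosis, a log2 difference of 0.44 ± 0.10 for MASLD. TAF11, a subunit of the general transcription factor TFIID, was at 26.3 ± 21.3, 52.4 ± 23.8 and 50.2 ± 20.9 (0.57 ± 0.14). PRKCB, a protein kinase C abundant in B cells, was lower in MASLD, at 266 ± 120, 154 ± 65.6 and 142 ± 69.4 (-0.62 ± 0.16). The clustered protocadherin PCDHGA2 was lower as well, at 19.6 ± 7.23, 8.85 ± 2.22 and 11.2 ± 6.22 (-0.28 ± 0.06); its last exons are shared with neighbouring genes of its cluster, so its reads are uncertain, and its counts show how the scale compresses low genes. None of these passed the threshold: in limma with Benjamini-Hochberg adjustment, 0 of 15958 genes did, and the smallest adjusted p was 0.468, for ABCB11 and PCDHGA2.

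ABCB11 (ENSG00000073734.10) is a protein-coding gene on the minus strand of chromosome 2 from 168915498 to 169031324, and its Healthy libraries ranged from 10.6 to 129 normalised reads, overlapping those of Steatosis (63.9 to 145) and Fibrosis (72.9 to 156). PCDHGA2 (ENSG00000081853.15) lies on chromosome 5 from 141338760 to 141512979, PRKCB (ENSG00000166501.14) on chromosome 16 from 23835946 to 24220611, and TAF11 (ENSG00000064995.18) on chromosome 6 from 34877462 to 34888089. Other genes with the smallest p were ZNF431 (0.34), TRIQK (0.29) and ZNF322 (0.26), all higher in MASLD, and the mitochondrial carrier SLC25A30 (-0.26), R3HDM2 (-0.28) and the poly(A)-binding protein PABPC1L (-0.28), all lower; their adjusted p in limma was 0.728. At an unadjusted p under 0.05 there were 1051 genes, 501 higher and 550 lower, where 797.9 is 0.05 of the genes tested. That figure takes no account of how genes vary together. Other splits of the libraries into groups of the same sizes gave a median of 706 such genes. No count-model test was run beside limma. The median SE was 0.0720, and for 97.3% of genes the 95% interval lay within 1.5-fold on the deposited scale, which compresses low genes and so sets no such limit on their read counts.

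**Figure D2:**
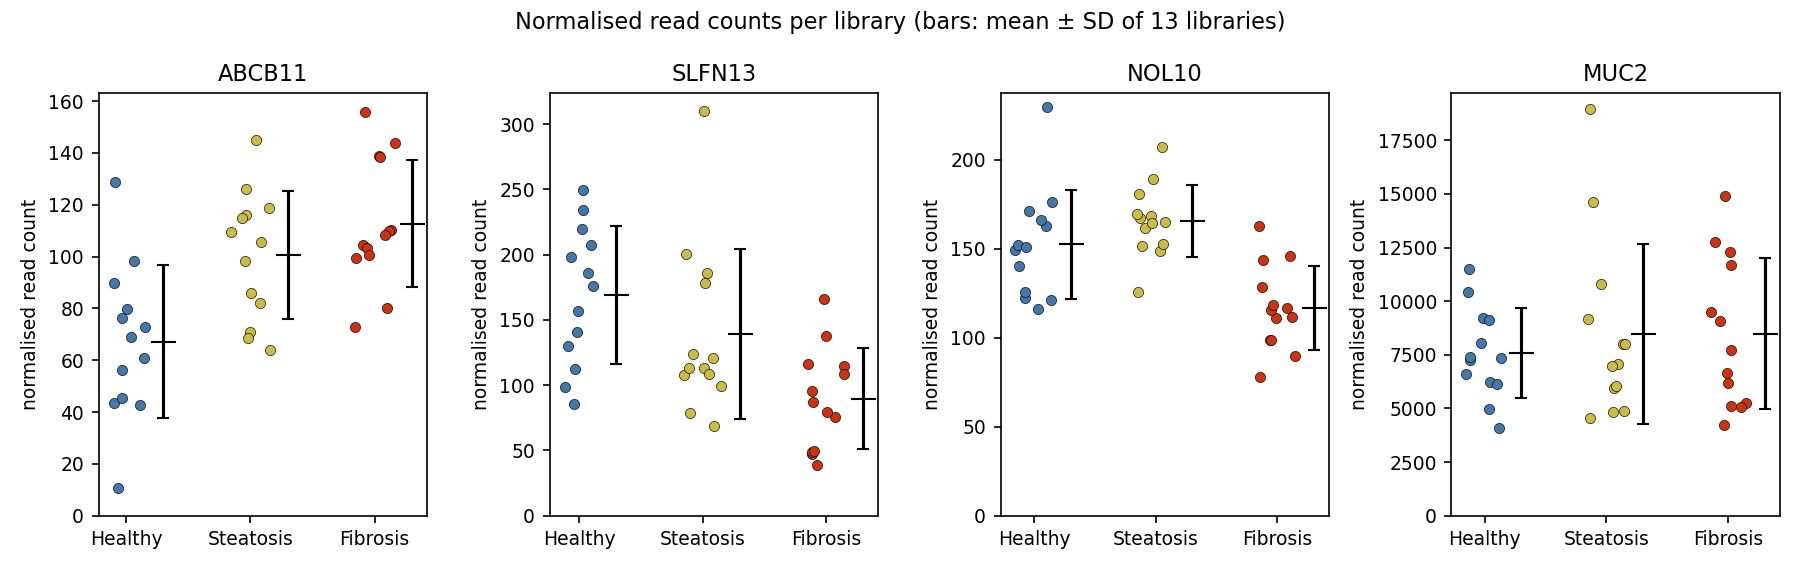
Normalised read counts of ABCB11, SLFN13, NOL10 and MUC2 in each library, with the mean and SD of the 13 libraries per group beside the points. No gene passed the adjusted threshold, and in each panel the groups' ranges overlap, as for ABCB11 in Healthy (10.6 to 129) and Fibrosis (72.9 to 156).

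Genes of the mucus layer and the epithelial junctions, which keep gut bacteria away from the tissue, were given in advance. MUC2, the gel-forming mucin of the colon, was at 7563 ± 2096 normalised reads in Healthy, 8452 ± 4199 in Steatosis and 8490 ± 3499 in Fibrosis (MASLD 0.09 ± 0.18). The mucus proteins FCGBP (0.18 ± 0.16) and CLCA1 (0.22 ± 0.31) and the junction protein OCLN (0.07 ± 0.10) likewise differed by little more than their SE or less. The junction scaffold TJP1 was at 533 ± 115, 629 ± 122 and 667 ± 252 (0.24 ± 0.11; unadjusted p = 0.0346, adjusted p = 0.746 in limma). The receptors for lipopolysaccharide, TLR4 (0.01 ± 0.11), and flagellin, TLR5 (-0.10 ± 0.08), and the antimicrobial lipocalin LCN2 (-0.07 ± 0.26) had 95% intervals that included 0. CLDN2 and REG1A were below the filter: CLDN2 reached 10 reads in 0 libraries (highest group mean 2.10) and REG1A in 1 (2.67).

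Of 40 gene lists, camera called 16 in MASLD against Healthy, 6 higher and 10 lower, and none of them held with an estimated correlation. All 26 T and natural killer cell genes were lower, by -0.14 on average, among them the surface receptor CD2 (-0.27 ± 0.12), the killer-cell pore protein PRF1 (-0.19 ± 0.09), IL7R and CD3E (adjusted p = 3.17e-06 in camera; adjusted p = 0.656 with an estimated correlation). B cell and follicle genes were lower for 19 of 21, with a mean of -0.25, including the B cell receptor chain CD79A (-0.45 ± 0.19), LTB (-0.47 ± 0.20) and PAX5 (adjusted p = 2.17e-05; adjusted p = 0.656 with an estimated correlation). Mast cell and eosinophil genes were lower for 10 of 13, led by the mast cell protease CPA3 (-0.39 ± 0.14). Plasma cell genes were lower for 16 of 19, though SDC1, which epithelium also expresses, was higher (0.15 ± 0.06). Macrophage genes were lower for 20 of 24, such as CSF1R (-0.26 ± 0.14), and fibroblast and matrix genes for 24 of 27, such as the collagen COL5A1 (-0.30 ± 0.13). Tuft cell genes were lower for 9 of 13, led by MATK (-0.21 ± 0.06). With an estimated correlation the adjusted p was 0.703 for macrophages and 0.656 for the mast cell, plasma cell, fibroblast and tuft cell lists. In Fibrosis 6 the mean scores of the fibroblast (-1.89), macrophage (-1.39) and plasma cell (-2.68) lists were below those of every other Fibrosis library (lowest -0.211, -0.225 and -1.05). Without it camera no longer called the fibroblast (mean -0.05 in place of -0.13; adjusted p = 0.0674), macrophage (-0.04 in place of -0.09; adjusted p = 0.311) and plasma cell (-0.08 in place of -0.19; adjusted p = 0.275) lists. Over 39 fits that each left out 1 library, the macrophage call ended in 12, the plasma cell call in 6 (mean -0.12 without Healthy 10) and the tuft cell call in 10 (mean -0.03 in place of -0.06 without Healthy 13; adjusted p = 0.181). The mast cell list stayed called, with a mean of -0.09 in place of -0.15 without Healthy 8.

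Junction genes were higher in MASLD for 24 of 27, with a mean of 0.09, among them the cingulin gene CGN (0.21 ± 0.10) and CLDN12 (0.15 ± 0.07), while CLDN15 was lower (-0.18 ± 0.07; camera adjusted p = 2.21e-05, and adjusted p = 0.656 with an estimated correlation). Goblet cell and mucus genes were higher for 24 of 25 (mean 0.12), such as C1GALT1C1, a chaperone needed for mucin glycosylation (0.13 ± 0.06), the transcription factors FOXA3 (0.15 ± 0.09) and SPDEF (0.15 ± 0.09), and SPINK4 (0.57 ± 0.38). Mature colonocyte genes were higher for 20 of 24, led by the carbonic anhydrase CA2 (0.29 ± 0.14), nuclear-encoded respiratory chain genes for 39 of 50, led by ATP5MC3 (0.16 ± 0.06), and cholesterol synthesis genes for 21 of 25, such as MSMO1 (0.22 ± 0.12). The adjusted p of these 4 lists in camera ran from 0.00069 to 0.0400, and each had an adjusted p = 0.656 with an estimated correlation. Within its group Fibrosis 6 had the highest junction score (0.801; others up to 0.187) and colonocyte score (1.38; others up to 0.317). Without it the colonocyte list was not called in MASLD (mean 0.05 in place of 0.10; camera adjusted p = 0.311). The junction mean was then 0.06 (adjusted p = 0.000502). The colonocyte call ended in 15 of 39 fits that each left out 1 library, and the cholesterol synthesis mean was 0.06 in place of 0.10 without Steatosis 7 (adjusted p = 0.0497).

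Ribosomal protein mRNAs were lower for 46 of 49, led by RPS19 (-0.18 ± 0.09), replication-dependent histone mRNAs for 34 of 36, led by H1-3 (-0.25 ± 0.11), and cell cycle genes for 26 of 30, led by RRM2 (-0.19 ± 0.10). Each was called by camera (adjusted p = 1.9e-05, 9.54e-06 and 0.00069) and each had an adjusted p = 0.656 with an estimated correlation. Without Fibrosis 6 the ribosomal protein mean was -0.04 in place of -0.09 (camera adjusted p = 0.00551). Without Healthy 9 the histone mean was -0.08 in place of -0.14 (0.0107) and the cell cycle mean -0.06 in place of -0.09 (0.0499). Red blood cell genes were higher for 6 of 6, with a mean of 0.31, among them the globins HBA2 (0.59 ± 0.22), HBA1 (0.51 ± 0.20) and HBB (0.45 ± 0.21); HBA1 and HBA2 are near-identical, so reads can be split between them (camera adjusted p = 0.00188; adjusted p = 0.594 with an estimated correlation). Adjusted over the list alone, 4 members passed, MATK, ABCB11, HBA2 and HBA1, against 0 over all genes. The remaining 24 lists were not called, among them bacterial sensing (12 higher and 13 lower of 25), antimicrobial defence (10 and 5 of 15), inflammatory cytokines (5 and 12 of 17), the interferon response (23 and 13 of 36) and the transmembrane mucins (6 and 1 of 7). In fry and in permutations of the list scores 0 lists passed in MASLD (smallest adjusted p 0.398 and 0.342), and 1 had an unadjusted p under 0.05 by permutation. The enteroendocrine, neutrophil and lipogenesis lists had a median and a mean of opposite sign.

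**Figure D3:**
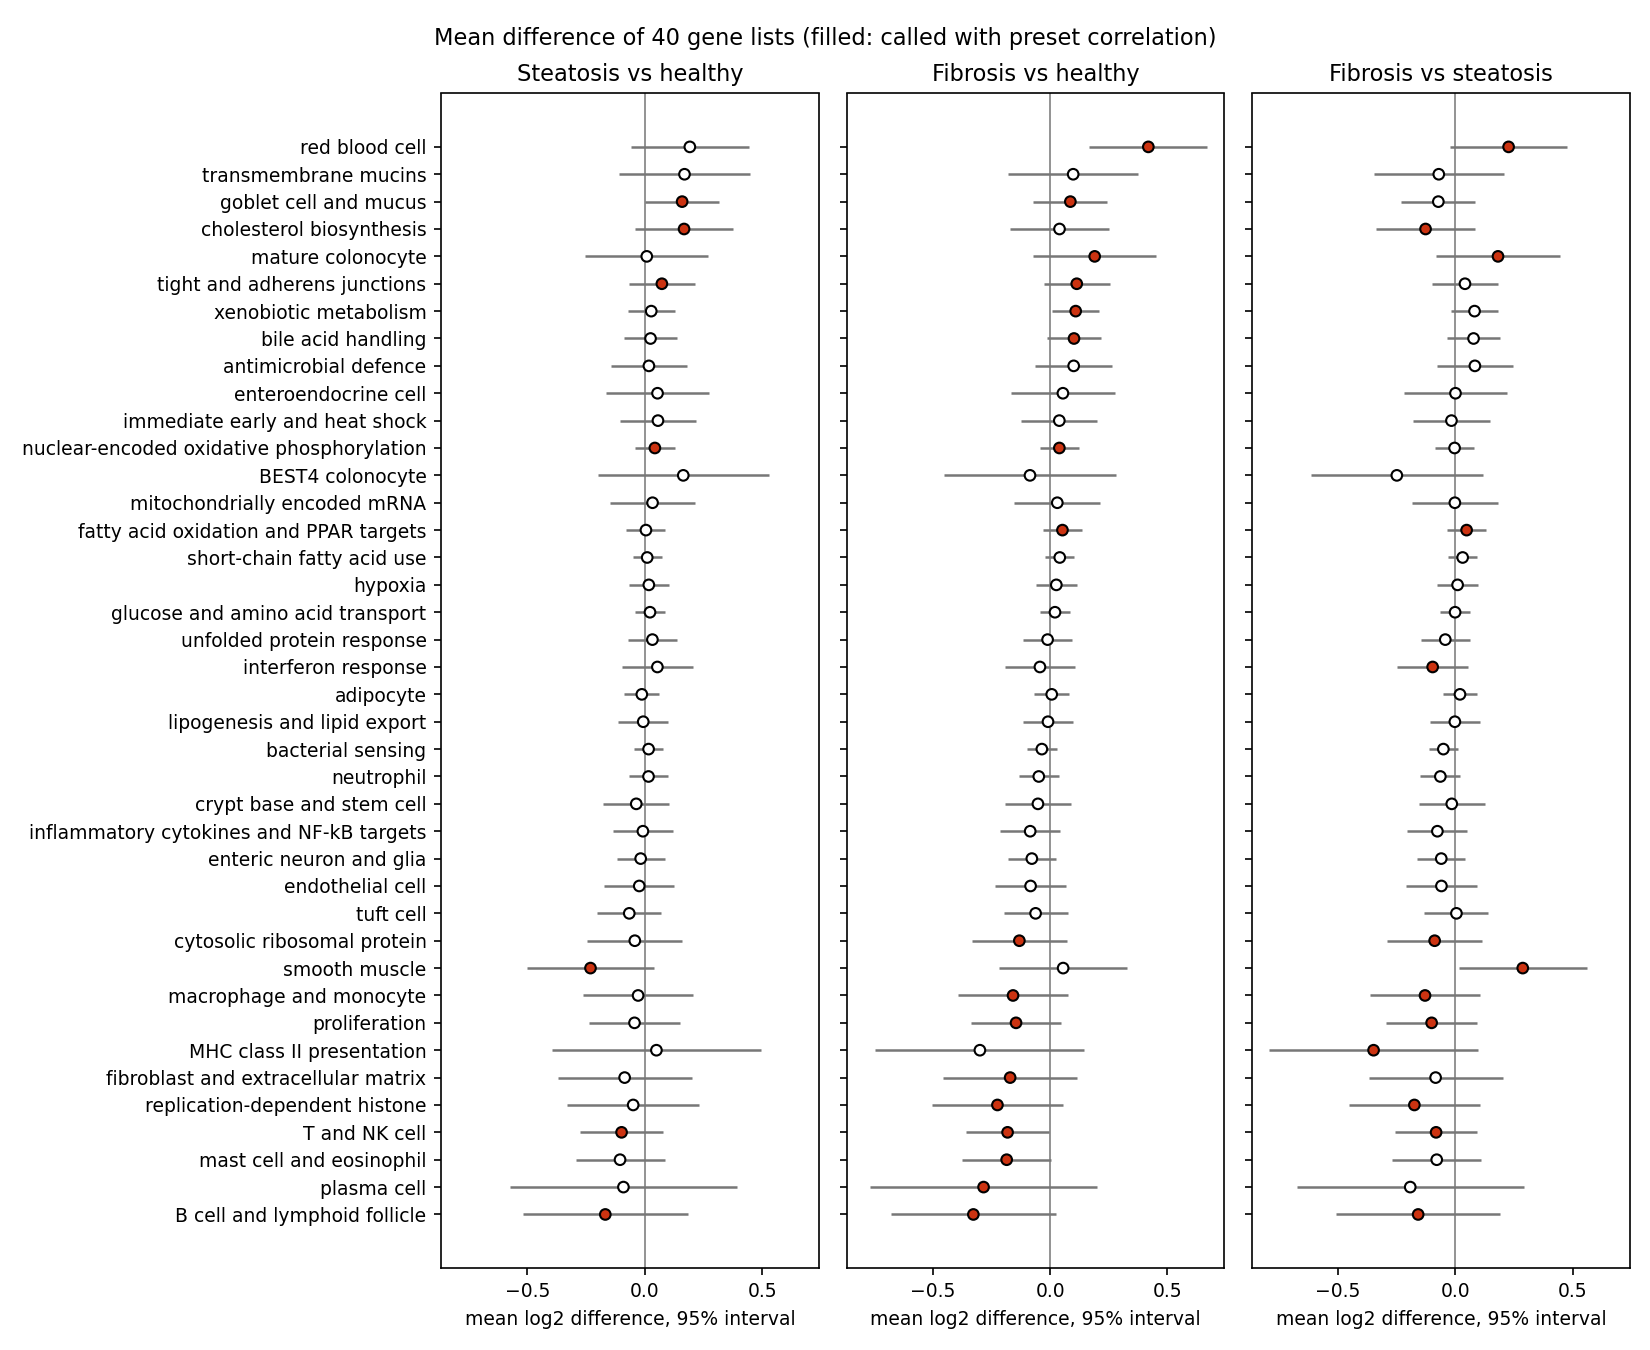
Mean log2 difference of each of the 40 gene lists with its 95% interval, in the comparisons of Steatosis with Healthy, Fibrosis with Healthy and Fibrosis with Steatosis. Filled points are lists called by camera at the preset correlation (7, 17 and 13 lists); 0 were called with an estimated correlation.

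The second comparison set the Steatosis label against Healthy. UPF2, a factor of nonsense-mediated mRNA decay, was higher in Steatosis (318 ± 44.0 in Healthy and 395 ± 69.7 in Steatosis; 0.26 ± 0.07), as were the spliceosome protein gene SNRPE (47.4 ± 10.4 and 68.5 ± 17.5; 0.27 ± 0.08), TAF11 (0.58 ± 0.17), TRIQK (0.32 ± 0.09) and ABCB11 (0.39 ± 0.11). The lysosomal chloride transporter CLCN7 was lower (371 ± 62.2 and 287 ± 57.5; -0.31 ± 0.08), and so were the growth factor VEGFB (87.6 ± 19.1 and 59.9 ± 14.3; -0.31 ± 0.08), PCDHGA2 (-0.31 ± 0.07), PABPC1L (-0.30 ± 0.09) and TGFB1I1, a focal adhesion protein of smooth muscle (-0.25 ± 0.07). UPF2 lies on chromosome 10 from 11920022 to 12043170 and CLCN7 on chromosome 16 from 1444934 to 1475580. In limma 0 genes passed, and the smallest adjusted p was 0.961. At an unadjusted p under 0.05 there were 784 genes (390 higher and 394 lower), where 797.9 is 0.05 of the genes tested. The median over other splits of the libraries into groups of the same sizes was lower, at 578 genes. No count-model test was run.

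Camera called 7 lists in Steatosis, 4 higher and 3 lower. Cholesterol synthesis genes were higher for 24 of 25, with a mean of 0.17, among them SC5D (0.23 ± 0.09), MSMO1 (0.32 ± 0.14), HMGCS1 (0.34 ± 0.16) and CYP51A1 (0.30 ± 0.14), all enzymes of the sterol pathway (adjusted p = 5.33e-06 in camera; adjusted p = 0.938 with an estimated correlation). Goblet cell and mucus genes were higher for 24 of 25, with a mean of 0.16, including SPINK4 (0.89 ± 0.44), the trefoil peptide TFF3 (0.30 ± 0.16) and the mucin-modifying enzyme ST6GALNAC1 (0.20 ± 0.11; camera adjusted p = 0.000118, and adjusted p = 0.938 with an estimated correlation). All 21 smooth muscle genes were lower, with a mean of -0.23, such as TAGLN (-0.45 ± 0.25), TPM2 (-0.43 ± 0.23) and LDB3 (-0.20 ± 0.10; camera adjusted p = 5.33e-06, and adjusted p = 0.938 with an estimated correlation). Junction genes (23 of 27) such as PARD3 (0.13 ± 0.06) and respiratory chain genes (38 of 50) such as ATP5MC3 (0.18 ± 0.07) were higher. T and natural killer cell genes (23 of 26) such as PRF1 (-0.20 ± 0.10) and B cell genes (19 of 21) such as LTB (-0.38 ± 0.23) were lower. Camera's adjusted p was 0.00337 for the junction, respiratory chain and T cell lists and 0.0120 for B cells, and each had an adjusted p = 0.938 with an estimated correlation. Adjusted over the list alone, 1 member passed, ABCB11, against 0 over all genes. Over 39 fits that each left out 1 library, 4 of the 7 lists were called in all. The B cell call ended in 8 fits (without Healthy 12, mean -0.10 in place of -0.17 and adjusted p = 0.142), and the T cell call without Healthy 12 (mean -0.06; adjusted p = 0.0631). The respiratory chain call ended without Healthy 12 (0.03; adjusted p = 0.0524) or Steatosis 7 (0.02; adjusted p = 0.150). Without Steatosis 7 the cholesterol synthesis mean was 0.09 in place of 0.17 (adjusted p = 0.0150).

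In Steatosis, fry and the permutation of list scores each passed 0 lists (smallest adjusted p 0.948 and 0.787), and 2 lists, goblet cell and smooth muscle, had an unadjusted permutation p under 0.05 (0.0294 and 0.0393). Median and mean differed in sign for 6 uncalled lists: antimicrobial defence, inflammatory cytokines, MHC class II, mature colonocyte, macrophage, and fatty acid oxidation; for lipogenesis the mean was opposite to the median and the test. Leaving out single libraries raised the number of lists called to 11 without Steatosis 1 or Healthy 3, 12 without Steatosis 3 or Steatosis 4, and 13 without Steatosis 13.

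The third comparison set the Fibrosis label against Healthy. SLFN13, an RNA-cleaving schlafen protein, was at 169 ± 52.8 normalised reads in Healthy and 89.6 ± 38.6 in Fibrosis (-0.63 ± 0.14), and TCF7, a transcription factor of naive and memory T cells, at 202 ± 78.2 and 111 ± 71.6 (-0.66 ± 0.17). R3HDM2 (547 ± 104 and 406 ± 54.9; -0.37 ± 0.08), WIPF3 (-0.22 ± 0.05) and SLC25A30 (-0.29 ± 0.07) were lower too. ABCB11 was higher (0.50 ± 0.11), as were the RNA-binding protein LIN28A (59.5 ± 5.57 and 74.8 ± 8.85; 0.18 ± 0.04), the zinc finger genes ZNF567 (0.31 ± 0.08) and ZNF431 (0.38 ± 0.10), and SAR1B, which drives export of lipoproteins from the endoplasmic reticulum (621 ± 57.4 and 739 ± 101; 0.22 ± 0.06). SLFN13 (ENSG00000154760.14) lies on chromosome 17 from 35435096 to 35448837 and TCF7 (ENSG00000081059.20) on chromosome 5 from 134114711 to 134151865. In limma 0 genes passed; the smallest adjusted p was 0.511, for ABCB11, LIN28A, SLFN13, R3HDM2 and WIPF3, and 0.573 for the others. At an unadjusted p under 0.05 there were 1266 genes, 575 higher and 691 lower, where 797.9 is 0.05 of the genes tested. The median over other splits of the libraries into groups of the same sizes was 760 genes. No count-model test was run.

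Camera called 17 lists in Fibrosis, 8 higher and 9 lower. All 36 replication-dependent histone mRNAs were lower, with a mean of -0.22, such as H1-3 (-0.34 ± 0.13) and H1-4 (-0.29 ± 0.13; camera adjusted p = 1.53e-09, and adjusted p = 0.534 with an estimated correlation). All 49 ribosomal protein mRNAs were lower, with a mean of -0.13, such as RPS6 (-0.37 ± 0.15) and RPL7 (-0.23 ± 0.11), and so were 28 of 30 cell cycle genes, such as TYMS (-0.26 ± 0.13) and MCM7 (-0.18 ± 0.10; adjusted p = 0.534 with an estimated correlation for both lists). T and natural killer cell genes were lower for 25 of 26, with a mean of -0.18, among them IL7R (-0.31 ± 0.12), the costimulator ICOS (-0.21 ± 0.08), CD2 (-0.35 ± 0.13) and ZAP70 (-0.37 ± 0.15). B cell genes were lower for 19 of 21, with a mean of -0.33, including CD79A (-0.58 ± 0.22) and PAX5 (-0.53 ± 0.25). Both had an adjusted p = 0.534 with an estimated correlation. Macrophage genes (21 of 24; CSF1R -0.40 ± 0.17), mast cell genes (10 of 13; CPA3 -0.45 ± 0.16), fibroblast genes (24 of 27; THY1 -0.42 ± 0.20) and plasma cell genes (16 of 19; IGHG4 -1.26 ± 0.43) were lower, with adjusted p = 0.534 for the first 3 and 0.552 for plasma cells with an estimated correlation. Fibrosis 6 had the lowest ribosomal protein score of the Fibrosis group (-1.27; others from -0.211), and the lowest histone score (-0.698; others from -0.383) and cell cycle score (-0.583; others from -0.277). Without Fibrosis 6 camera called none of 4 of these lists: ribosomal protein (32 of 49 lower, mean -0.03; adjusted p = 0.145), macrophage (mean -0.05 in place of -0.16; adjusted p = 0.263), fibroblast (16 of 27 lower, mean -0.02 in place of -0.17; adjusted p = 0.636) and plasma cell (mean -0.07 in place of -0.28; adjusted p = 0.749). The plasma cell call also ended without Fibrosis 7 (adjusted p = 0.103), Healthy 10 (0.0816) or Healthy 12 (0.0753).

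Higher in Fibrosis were mature colonocyte genes (20 of 24, mean 0.19), such as CA2 (0.48 ± 0.16), HSD17B2 (0.24 ± 0.10) and SELENBP1 (0.25 ± 0.12), and xenobiotic metabolism genes (22 of 30, mean 0.11), such as the quinone reductase NQO1 (0.46 ± 0.15) and the cytochromes CYP2S1 (0.34 ± 0.13) and CYP2C18 (0.27 ± 0.12). Junction genes (24 of 27) such as CLDN4 (0.30 ± 0.14) and EPCAM (0.17 ± 0.08), and goblet genes (21 of 25) such as FCGBP (0.32 ± 0.18), were higher as well. Bile acid genes were higher for 13 of 16, though the bile acid receptor NR1H4 was lower (-0.19 ± 0.09), fatty acid oxidation genes for 26 of 35, such as PPARD (0.33 ± 0.16), with UCP2 lower (-0.25 ± 0.13), and respiratory chain genes for 36 of 50. With an estimated correlation the respiratory chain list had an adjusted p = 0.552, and the other 6 lists an adjusted p = 0.534. Without Fibrosis 6 camera no longer called the colonocyte (mean 0.09; adjusted p = 0.110), xenobiotic (0.07; adjusted p = 0.156), goblet (0.07; adjusted p = 0.16), bile acid (0.05 in place of 0.10; adjusted p = 0.305) and fatty acid oxidation (0.04 in place of 0.05; adjusted p = 0.156) lists. The junction mean was then 0.05 in place of 0.11 (adjusted p = 0.0101). Leaving out 1 library at a time ended the goblet call in 12 of 39 fits (mean 0.05 without Fibrosis 3) and the fatty acid oxidation call in 9. The bile acid call also ended without Healthy 1 (adjusted p = 0.0546). The respiratory chain call ended without Fibrosis 12 (mean 0.02 in place of 0.04; adjusted p = 0.0881) or Healthy 12 (0.03; adjusted p = 0.0555). Red blood cell genes were higher for 6 of 6, with a mean of 0.42, carried by HBA2 (0.83 ± 0.25), HBA1 (0.66 ± 0.23) and HBB (0.61 ± 0.24; camera adjusted p = 0.000311, and adjusted p = 0.221 with an estimated correlation). Adjusted over the list alone, 7 members passed, namely the 3 globins, ABCB11, MATK (-0.23 ± 0.07), the chemokine CCL20 (-0.41 ± 0.14) and the cytokine IL18 (0.28 ± 0.10), against 0 over all genes.

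In Fibrosis against Healthy, fry and permutations of the list scores passed 0 lists (smallest adjusted p 0.0821 and 0.0748, both for red blood cell genes), and 1 list had an unadjusted permutation p under 0.05. The neutrophil and lipogenesis lists had a median and a mean of opposite sign. Without Fibrosis 6, 9 lists were called in place of 17, and 8 of the 9 were among the 17. The other was the smooth muscle list (mean 0.16 in place of 0.06; camera adjusted p = 7.81e-05, and adjusted p = 0.768 with an estimated correlation). Over 39 fits that each left out 1 library, 7 of the 17 lists were called in all.

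**Figure D4:**
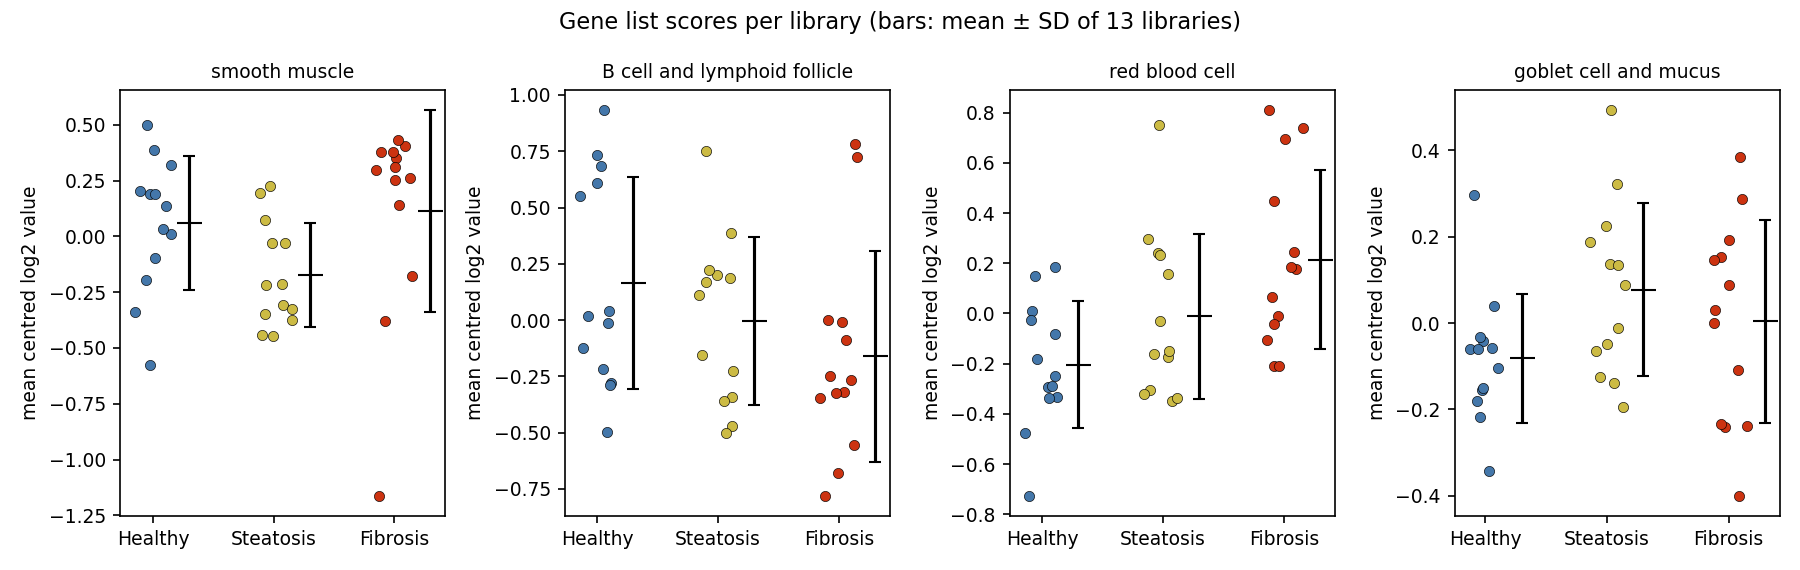
Mean centred log2 value of the smooth muscle, B cell and follicle, red blood cell, and goblet cell lists in each library, with the mean and SD of the 13 libraries per group. The lowest smooth muscle score, -1.16, belongs to Fibrosis 6.

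The last comparison set Fibrosis directly against Steatosis. NOL10, a nucleolar protein, was at 117 ± 23.7 normalised reads in Fibrosis and 165 ± 20.05 in Steatosis (-0.36 ± 0.07), and the spliceosome genes SNRPE (42.2 ± 12.3 and 68.5 ± 17.5; -0.36 ± 0.08) and SNRPB2 (80.5 ± 18.5 and 112 ± 11.6; -0.31 ± 0.07) were lower in Fibrosis too. IL17REL (-0.47 ± 0.12) and the mRNA export factor THOC7 (-0.22 ± 0.05) followed. ASXL2, a chromatin regulator, was higher in Fibrosis (611 ± 105 and 414 ± 108; 0.51 ± 0.11), as were the smooth muscle potassium channel subunit KCNMB1 (188 ± 23.2 and 149 ± 15.9; 0.25 ± 0.06), the Wnt-enhancing secreted protein RSPO2 (62.7 ± 11.9 and 42.0 ± 12.3; 0.30 ± 0.07), LIN28A (0.18 ± 0.04) and TMEM35A (0.27 ± 0.07). NOL10 (ENSG00000115761.16) lies on chromosome 2 from 10570766 to 10689987 and ASXL2 (ENSG00000143970.17) on the same chromosome from 25733753 to 25878516. In limma 0 genes passed, and the adjusted p was 0.144 for NOL10, 0.167 for SNRPE and SNRPB2, and 0.186 for ASXL2. At an unadjusted p under 0.05 there were 932 genes (453 higher and 479 lower), where 797.9 is 0.05 of the genes tested. The median over other splits of the libraries into groups of the same sizes was 842 genes. No count-model test was run. NOL10 passed when Healthy 4 (adjusted p = 0.0387 in limma) or Fibrosis 4 (0.0298) was left out.

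Camera called 13 lists between Fibrosis and Steatosis, 4 higher in Fibrosis and 9 lower. Smooth muscle genes were higher for 20 of 21, with a mean of 0.29, among them KCNMB1, the calponin CNN1 (0.39 ± 0.14) and LDB3 (0.27 ± 0.10; camera adjusted p = 4.56e-10, and adjusted p = 0.694 with an estimated correlation). Colonocyte genes were higher for 19 of 24, led by the water channel AQP8 (0.87 ± 0.26), with MS4A12 lower (-0.67 ± 0.28). Red blood cell genes (5 of 6; HBA2 0.47 ± 0.25) and fatty acid oxidation genes (25 of 35, with ACSL1 lower at -0.26 ± 0.11) were the others; these 3 lists had an adjusted p = 0.694 with an estimated correlation. Histone mRNAs were lower for 35 of 36, such as H2BC17 (-0.36 ± 0.17), cholesterol synthesis genes for 24 of 25, such as SC5D (-0.20 ± 0.09), and cell cycle genes for 26 of 30. The interferon response was lower for 26 of 36, such as IFI6 (-0.37 ± 0.16), IFI44L (-0.39 ± 0.18) and XAF1 (-0.29 ± 0.14), and MHC class II presentation for 9 of 11 (mean -0.35), such as CD74 (-0.45 ± 0.25) and its transcriptional activator CIITA (-0.34 ± 0.21). Macrophage genes (20 of 24) and T and natural killer cell genes (20 of 26; ICOS -0.27 ± 0.08) were lower too. With an estimated correlation these 7 lists had an adjusted p = 0.694. Ribosomal protein (40 of 49; RPS6 -0.29 ± 0.15) and B cell genes (18 of 21; MS4A1 -0.48 ± 0.29) completed the lower lists, with an adjusted p = 0.769 for both with an estimated correlation. Only the histone and smooth muscle lists were called in all 39 fits that each left out 1 library. Without Fibrosis 6 the ribosomal protein list turned (28 higher and 21 lower, mean 0.01; camera adjusted p = 0.224). The macrophage mean was then -0.02 in place of -0.13 (adjusted p = 0.594), the colonocyte mean 0.08 in place of 0.18 (0.151) and the B cell mean -0.11 in place of -0.16 (0.178). The MHC class II (-0.26), T cell (-0.05) and cell cycle (-0.06) lists then had an adjusted p = 0.0761, red blood cells (0.21) 0.107 and fatty acid oxidation (0.03) 0.202, so none of these was called. Without Steatosis 3 the interferon mean was -0.05 in place of -0.10 (adjusted p = 0.183). Calls ended for the MHC class II (-0.28) and cholesterol synthesis (-0.09) lists (adjusted p = 0.0568 for both) and for the B cell (-0.14), macrophage (-0.11) and red blood cell (0.20) lists (0.0587 for each). They ended as well for the T cell (-0.06; 0.0798), cell cycle (-0.06; 0.0870) and fatty acid oxidation (0.03; 0.126) lists. The histone mean was then -0.11 in place of -0.18 (0.00770). Other calls ended without Steatosis 9 (interferon, mean -0.05; adjusted p = 0.246), Steatosis 7 (cholesterol synthesis, -0.05; 0.166), Steatosis 1 (B cell, -0.10; 0.249) and Fibrosis 7 (T cell, -0.05; 0.0986). In all, the B cell call ended in 11 fits, fatty acid oxidation in 10, red blood cell in 9, T cell in 6, and MHC class II and macrophage in 4 each.

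Between Fibrosis and Steatosis, 6 members passed when adjusted over the list alone, against 0 over all genes, among them AQP8, ICOS, CNN1, KCNMB1, and SPIB (-0.59 ± 0.17), a transcription factor listed for BEST4-positive colonocytes that B cells and M cells also express. Fry and permutations passed 0 lists (smallest adjusted p 0.661 and 0.721), and 0 had an unadjusted permutation p under 0.05. The mean was opposite in sign to the median in the transmembrane mucin, crypt base, tuft cell, respiratory chain and hypoxia lists. Leaving out Fibrosis 6 or Steatosis 3 left 4 lists in place of 13, namely smooth muscle and histone in both fits, with cholesterol synthesis and interferon in the first and colonocyte and ribosomal protein in the second. Without Fibrosis 6, whose smooth muscle score of -1.16 was the lowest of its group, the smooth muscle list had a mean of 0.39 and an adjusted p = 0.0360 with an estimated correlation, the lowest of the 39 fits that each left out 1 library (up to 0.777), and that library was singled out after the data were seen.

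The Steatosis and Fibrosis differences from Healthy correlated across genes with r = 0.534, and 68.9% of genes had the same sign. Both share the Healthy libraries. Simulated groups with no effect that shared their controls gave a mean r of 0.507 (0.232 to 0.690) and 67.0% of the same sign. Those controls were drawn at random from the residuals of all 39 libraries, Fibrosis 6 among them. Their spread can therefore differ from that of the Healthy libraries, and the simulated range is only a rough guide. The covariance was 0.00774 observed, within the 0.00227 to 0.0106 of the simulations (mean 0.00620, a difference of 0.00154). With the Healthy libraries split between the comparisons, r averaged 0.117 (-0.00923 to 0.201) and the covariance 0.00232 (-0.00021 to 0.00380). Genes are not independent replicates, so no p is given.

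Among library measures, 30 comparisons of groups gave 0 calls by permutation tests with Benjamini-Hochberg adjustment, and 4 had an unadjusted p under 0.05. Fibrosis libraries had 19179 ± 358 detected genes against 19462 ± 149 in Healthy (p = 0.00527, adjusted p = 0.158 in the permutation test) and 19432 ± 140 in Steatosis (p = 0.0121, adjusted p = 0.177). Globin mRNAs took 0.00734 ± 0.00557% of reads in Fibrosis and 0.00323 ± 0.00233% in Healthy (permutation p = 0.0177, adjusted p = 0.177). The 10 most abundant genes took 10.3 ± 0.732% in Fibrosis and 9.76 ± 0.589% in Steatosis (permutation p = 0.0423, adjusted p = 0.247). Without Fibrosis 6, the Fibrosis libraries had 19256 ± 235 detected genes, 10.2 ± 0.563% in the 10 most abundant genes and 0.00762 ± 0.00573% in globin mRNAs. These comparisons were not tested again without it. Estimated depth was 6.20 ± 0.340 M reads in Healthy, 6.29 ± 0.539 M in Steatosis and 5.83 ± 0.612 M in Fibrosis.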

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

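Chosen only after the result was seen were the splits for the numbers of genes, both tests on Fibrosis 6 and the permutation of red blood cell scores. So were the biopsy content score (with and without Fibrosis 6) for the lists in MASLD, and the counts of splits with at least 8 or 12 lists. The estimated correlation had been planned for all lists, but its use to weigh a cause of the MASLD lists came after. The other splits and tests had been fixed before their results were seen.

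Differences between the 2 disease labels drew attention to 3 lists, because their mean differences from Healthy had opposite signs and camera called the difference between Fibrosis and Steatosis. Smooth muscle genes differed by 0.287 (mean log2, Fibrosis minus Steatosis), from -0.23 in Steatosis and 0.06 in Fibrosis. MHC class II presentation differed by -0.349, from 0.05 and -0.30, and the interferon response by -0.0973, from 0.05 and -0.04. Camera's adjusted p was 4.56e-10, 0.0162 and 0.00586, and with an estimated correlation each list had an adjusted p = 0.694. For MHC class II the direction in Steatosis is not settled, since the median was -0.12 with 7 of 11 genes lower. Without Steatosis 3 its mean in Steatosis was -0.01 and that of the interferon response 0.01, and camera called neither difference between Fibrosis and Steatosis (-0.28, adjusted p = 0.0568, and -0.05, adjusted p = 0.183). The MHC class II call also ended without Fibrosis 6 (-0.26; adjusted p = 0.0761), Steatosis 4 (0.0504) or Steatosis 12 (0.0576), and the interferon call without Steatosis 9 (-0.05; adjusted p = 0.246).

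Gene lists called in MASLD against Healthy, 16 in number, were weighed first. Lists whose members vary together between libraries are a candidate explanation, since 0 of the 16 kept an adjusted p under 0.05 with an estimated correlation, and 21 of 100 splits of the libraries into groups of the same sizes, the real one included, gave at least 16 lists (up to 23 in another split), so chance could not be excluded. Depth stays open, with 16 lists called when estimated depth was a covariate. Without Fibrosis 6, 12 lists were called, all among the 16. The T cell (-0.13), B cell (-0.22) and goblet (0.12) means then stayed near their values with it, so Fibrosis 6 alone does not account for those lists. The fibroblast, macrophage, plasma cell and colonocyte calls ended, and the ribosomal protein (-0.04) and junction (0.06) means shrank. Its part in the other lists stays open. The bound set beforehand for both tests, at least 8 lists, was wrong, because 83 of 99 other splits gave at least 8, 49 at least 12 and 20 at least 16. Varying amounts of epithelium and lamina propria could not be decided. Their score was the mean of the lists of cells of the lamina propria and deeper wall, minus that of the colonocyte, goblet and junction lists. With it as a covariate, 4 of the 7 called lists outside the score stayed called. The score differed from Healthy by -0.429 in Steatosis and -0.705 in Fibrosis (permutation adjusted p = 0.114 for both). Fibrosis 6 had a score of -4.82 (others from -1.74), and without it the Fibrosis difference was -0.331 (adjusted p = 0.225), nearer to Healthy than Steatosis was. A change of the mucosa with disease stays open and was not tested apart from these.

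Fibrosis 6 was weighed next. A biopsy with little lamina propria, the connective tissue under the epithelium, may account for it: 8 of 9 lists of cells of the lamina propria and deeper wall had their lowest score in the Fibrosis group in this library, while its junction and mature colonocyte scores were the highest. Not all epithelial lists were high in it. Its goblet score was 0.192 (other Fibrosis libraries up to 0.385). Its crypt base and stem cell score was -0.616, the lowest of all libraries (others from -0.333). Low depth is argued against, because 9 of the 12 other Fibrosis libraries had a lower estimated depth. This library also had the fewest detected genes, 18253 against at least 18671 in the others, and its mitochondrial mRNAs took 9.08% of reads. RNA quality was not tested as an explanation. No biological explanation was tested, since the labels set nothing apart about this library.

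Globin mRNAs in Fibrosis against Healthy, with a mean log2 difference of 0.699 over HBA1, HBA2 and HBB, were weighed last. Blood in the biopsies may be the source: across the 39 libraries, after removing group means, the 3 genes correlated pairwise with r of at least 0.760 (HBA1 with HBA2) and up to 0.871 (HBA1 with HBB), although reads split between HBA1 and HBA2 could add to the correlation of that pair. Depth is argued against, since the difference was 0.789 with estimated depth as a covariate. Chance could not be excluded: the permutation p of the list score was 0.00187, and 0.0748 after adjustment over the 40 lists. More blood in the mucosa of people with fibrosis, as opposed to bleeding at biopsy, stays open and was not tested.

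For each result 100 splits of the libraries were compared, the real grouping and 99 others, and each number of splits given includes the real one. They did not exclude chance for the counts over 0; for the unadjusted genes in Fibrosis the share was at the limit, 5 of 100. For the 0 genes past the threshold they decide nothing, since all 100 splits must give at least 0; the other splits gave up to 3, 1, 1 and 3 genes for MASLD, Steatosis and Fibrosis against Healthy and for Fibrosis against Steatosis. As many genes with an unadjusted p under 0.05 came from 20 splits for MASLD (1051 genes, highest other 1765), 13 for Steatosis (784, 1187), 5 for Fibrosis (1266, 1705) and 36 for Fibrosis against Steatosis (932, 2040). As many lists came from 77 splits for Steatosis (7 lists, highest other 18), 19 for Fibrosis (17, 21) and 48 for Fibrosis against Steatosis (13, 25).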

How the results depend on the processing

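Chosen after the data were seen were upper-quartile factors, log2 of the normalised count plus 1 or 10, array weights, the filter at 50, the fits without Fibrosis 6, 7 and 8, the depth, residual-component and biopsy content covariates, and the permutation of list scores; the other alternatives were fixed before. The planned count-model tests, voom weights, surrogate variables and size factors for counts were not run, because whole reads could not be recovered; array weights gave no list test.

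The number of genes past the threshold was 0 in all 4 comparisons under every alternative run except 2 kinds. With 2 residual principal components as covariates, 11 genes passed in MASLD, 83 in Fibrosis against Healthy and 3 in Fibrosis against Steatosis, and 20 lists in the latter. These components leave the fold changes as they were and lower the spread. As many genes came from 14 of 100 splits, the real one included, for MASLD and 8 of 100 for Fibrosis, so chance could not be excluded. The other splits gave a median of 0 genes for both, but up to 343 for MASLD and up to 504 for Fibrosis. Splits that call so many genes point to a structure of the samples or to the lowered spread itself, which was not tested. Leaving out each library in turn gave 0 to 0 genes in the comparisons with Healthy and 0 to 1 in Fibrosis against Steatosis (NOL10, without Healthy 4 or Fibrosis 4).

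Lists depended on the test: with an estimated correlation, with fry and with permutation of list scores, 0 passed in each comparison, against 16, 7, 17 and 13 with camera. The self-test shows the reason in part, since camera at the preset correlation called 11.2 unchanged lists on average. Without Fibrosis 6, 7 and 8, the libraries with the fewest detected genes, 9 lists were called in Fibrosis against Healthy and 8 against Steatosis. With the biopsy content score as a covariate, 5 were called in MASLD, 7 in Fibrosis and 8 in Fibrosis against Steatosis. That score is made from some of the same lists, so it removes part of their own differences and these counts do not test it. Among the 28 lists outside the score, calls went from 7 to 4 in MASLD and from 8 to 4 in Fibrosis. They went from 8 to 5 in Fibrosis against Steatosis and from 2 to 3 in Steatosis. Leaving out each library gave 12 to 18 lists in MASLD, 6 to 13 in Steatosis (11 without Steatosis 1 or Healthy 3, 12 without Steatosis 3 or 4, 13 without Steatosis 13), 9 to 20 in Fibrosis (9 without Fibrosis 6), and 4 to 18 in Fibrosis against Steatosis (4 without Steatosis 3 or Fibrosis 6). Of 9 and 4 lists called without Fibrosis 6 in the Fibrosis comparisons, 8 and 4 had been called with it. The cause was not tested beyond this. Splitting the Healthy libraries between the Steatosis and Fibrosis comparisons lowered r from 0.534 to 0.117. The split ended the sharing of controls and also left fewer Healthy libraries in each comparison, and these changes were not tested apart.

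For the named genes, 2588 of 2614 values kept their direction and side of the threshold, 13 reversed and 13 passed it, 11 of these with residual components. All reversals were of genes near 0 in MASLD: TLR4 (-0.00464 without mitochondrial and ribosomal protein genes), LCN2 (0.0251 without Fibrosis 6, 7 and 8, and 0.0635 with the content score), MUC2 (-0.107) and OCLN (-0.0358), both with the content score. That score is made in part from the goblet and mucus list and the junction list. As a covariate it can therefore take up part of the difference of a mucus gene such as MUC2 or a junction gene such as OCLN. Leaving out libraries moved TLR4 from -0.0422 to 0.0667, LCN2 from -0.141 to 0.142, CLCA1 from 0.0222 (without Healthy 9) to 0.357 (Healthy 11), MUC2 from 0.0242 (Healthy 1) to 0.147 (Healthy 9) and OCLN from 0.0263 (Fibrosis 6) to 0.0951 (Healthy 5). The cause was not tested.

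The labels number libraries 1 to 13 in each group, but the numbers do not pair them: same-numbered libraries deviated together with a mean r of 0.00600, 4 of 39 pairs lay over 0.1, and 2 of 39 libraries matched best with their own number. With the number as a replicate block, 0 genes and 16, 8, 17 and 13 lists passed. At these group sizes and depths, 32.9% of genes given the smallest simulated change were recovered in simulated MASLD comparisons. Each simulation changed 200 genes at once and gave 149.9 calls on average, which eases the Benjamini-Hochberg limit. Recovery where only a few genes change was not simulated and can be lower.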

Other observations

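The fits without Fibrosis 6 were chosen after that library had been seen to stand apart.

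Smooth muscle genes mark muscle of the bowel wall, and their level can depend on how deep a biopsy reaches. Their mean scores (± SD) were 0.03 ± 0.30 in Healthy (n = 13), -0.20 ± 0.23 in Steatosis (n = 13) and 0.19 ± 0.25 in Fibrosis without Fibrosis 6 (n = 12). Scores lay above 0 in 8, 3 and 10 libraries. Fibrosis and Steatosis then differed by 0.39 on the log2 scale, higher for 20 of 21 genes, with an adjusted p = 0.0360 in camera with an estimated correlation and a permutation p of 0.00092 (adjusted p = 0.0368 over the 40 lists). This passed in 1 of 39 fits that left out 1 library each (adjusted p from 0.0360 to 0.777), so it rests on the choice to leave out Fibrosis 6. In the same fit the enteric neuron and glia list had a mean of -0.02 (7 genes higher and 8 lower), and the fibroblast list 0.07 (20 higher and 7 lower). Biopsy depth was not measured, and no test here separates it from a change of the tissue.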
